A study of Mus musculus with 2 samples.

How the data were processed

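T cell receptor (TCR) transcripts were sequenced from single CD4+ T cells sorted from mouse liver 60 days after transplantation. Per the labels, the mice with chronic graft-versus-host disease (GVHD) were BALB/c recipients of B6 grafts. The labels give 2 libraries, 1 from mice with chronic GVHD and 1 from mice without GVHD. How many mice were pooled into each library, and how the mice without GVHD were prepared, is not given in the sources used here. The tissue label of both samples is liver, whereas the wording on RNA preparation speaks of lymphocytes of the thymus; the tissue label was followed.

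Per the submitters' processing notes, the reads were processed with Cell Ranger 3.1.0 and the mm10 build. The V(D)J reference and its settings are not given in the sources used here. The deposited contig tables list, for each barcode, the assembled TRA and TRB contigs with their V, J and C segments, CDR3 sequence, quality calls, read counts and UMI counts. Per the file headers these values are counts of reads and of unique molecular identifiers (UMIs) per contig, not normalized. The deposited consensus tables give a chain sequence for each clonotype defined by Cell Ranger. They were used only for totals and to count shared clonotypes in the alternative by Cell Ranger identifier.

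The main cell set held barcodes called as cells with at least 1 TRA contig and at least 1 TRB contig that was productive, high-confidence and full-length. Where a cell had several such contigs of a chain, the contig with the most UMIs was taken, with ties settled by reads and then by contig name. A clonotype was defined by V segment, J segment and CDR3 nucleotide sequence of both chains. An expanded clonotype held 2 or more cells. Because repeated clonotypes become more frequent as more cells are sampled, expanded shares and numbers of distinct clonotypes were compared after thinning both libraries to 4942 paired cells, as the mean of 100 seeded draws. Segment usage and CDR3 measures counted each clonotype once. For TRAV, the near-identical copies of the duplicated locus (names with D or N) were collapsed into a subgroup.

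The groups, the comparisons, the lists of segments, the rule for named segments and most alternatives were set before the data were examined. Named segments were those with at least 2% of clonotypes in at least 1 library and the largest or smallest ratio between libraries: 4 each way for TRBV and for TRAV, 2 for TRBJ and 3 for TRAJ. All members of the lists and the 5 largest clonotypes of each library were named as well. The list of segments that respond to the superantigens of endogenous mouse mammary tumor viruses (Mtv) held 5 members: TRBV26, TRBV12-1, TRBV12-2, TRBV16 and TRBV15. A comparator list held 6 members: TRBV13-1, TRBV13-2, TRBV13-3, TRBV19, TRBV1 and TRBV2. Invariant natural killer T (iNKT) receptors were read as TRAV11 or TRAV11D joined to TRAJ18 in any productive TRA of the cell, dominant or not, and those of mucosal-associated invariant T (MAIT) cells as TRAV1 joined to TRAJ33. Distances in segment usage are total variation distances, in percent. Non-productive TRB rearrangements were full-length, high-confidence contigs of called cells with both a V and a J segment, each counted once per Cell Ranger clonotype. A stricter set kept those with at least 2 UMIs whose CDR3 was not also found in a productive contig of the library.

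With 1 library per group there is no replicate error, no p-value and no replicate check, and each difference compares these libraries. Shares are given with exact (Clopper-Pearson) 95% intervals, and ratios with exact conditional 95% intervals. All intervals and limits cover counting error only. A share of 0 is given with the limit that 3 counts would set. Values are limited by the number of cells, 4942 and 8191 paired cells, and for TRA by a median of 3 and 4 UMIs per cell.

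Alternatives covered cells with exactly 1 chain of each kind, minimums of 2 and 5 UMIs in both chains, removal of cells with 2 or more TRB as possible doublets, removal of barcodes or clonotypes found in both libraries, clonotypes by TRB alone over all cells with a usable TRB, by Cell Ranger identifier or by amino acids, removal of the largest clonotype, deeper thinning, expansion from 3 cells, counting by cell and other cuts for the CDR3 and TRAJ measures. Those that leave out TRBV26, split clonotypes by size use the CDR3 start of TRBV12-2, read iNKT receptors from the dominant TRA only, group the paired cells by TRB or thin all paired cells to the number left by 5 UMIs were added after the data were seen. The procedure was tested on simulated data built from the clonotype sizes of the library without GVHD. In that test 3153 of 3153 clonotypes were recovered from 8191 cells, and thinning missed the expected number of clonotypes by 0.0805%. Each simulated cell carried 1 true TRA and its true TRB, with more UMIs than any wrong TRB, so full recovery was fixed in advance. The test thus checks the code and cannot show clones split by a second TRA. In the data, 3153 paired clonotypes without GVHD held 2572 distinct TRB nucleotide sequences, and 4482 with chronic GVHD held 4308.

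Segment positions are those of the RefSeq annotation of GRCm38.p6, the assembly called mm10. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Gene expression of the same cells was not analysed here.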

Results

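The TCR repertoire of CD4+ T cells in the liver was read from 2 libraries taken at day 60 after transplantation. Of these, 1 was from mice with chronic GVHD and 1 from mice without GVHD. Chronic GVHD is a late complication of transplantation in which donor T cells attack tissues of the recipient. The cells were sorted for the MHC class I molecule H2Kb, the TCR and CD4. H2Kb marks donor cells in the mice with chronic GVHD. Whether it does so in the mice without GVHD cannot be told, as their preparation is not given. The comparison asks how clonal composition and segment usage of these sorted CD4+ T cells differ with disease. The chronic GVHD library held 6766 called cells with 129059 UMIs in its contig table, and the library without GVHD 10197 called cells with 246279 UMIs. Reads in these tables numbered 35107760 and 34875532, or 272 and 142 reads per UMI. Both a usable TRA and a usable TRB were found in 73.0% of called cells with chronic GVHD (95% interval 72.0 to 74.1%, 4942 cells) and in 80.3% without (79.5 to 81.1%, 8191 cells). TRA was the limiting chain, present in 75.4% and 85.1% of called cells, while TRB was present in 97.6% and 95.2%. Among paired cells, 9.77% and 11.9% carried 2 or more productive TRB. No immunoglobulin, TRG or TRD contig was listed in either library.

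Clonal expansion was far greater in the library without GVHD. Of its paired cells, 71.7% (70.7 to 72.7%) belonged to clonotypes of 2 or more cells, against 15.4% (14.4 to 16.4%) with chronic GVHD. At an equal number of 4942 paired cells the share without GVHD was 66.7%, with draws from 65.7 to 68.6%, which is 4.33 times the chronic GVHD share. The chronic GVHD library then held 4482 distinct clonotypes and the other 2160, a ratio of 2.08. Clonotypes of 10 or more cells numbered 2 with chronic GVHD and 111 without, and those of 50 or more cells 0 and 16. The latter held 19.8% of paired cells without GVHD (19.0 to 20.7%). Single-cell clonotypes held 84.6% of cells with chronic GVHD and 28.3% without. The probability that 2 random cells shared a clonotype was 0.00977% with chronic GVHD and 0.522% without. By TRB alone, over all 6605 and 9708 cells with a usable TRB and thinned to 6605, the shares were 30.1% and 76.7%. Within the paired cells, a choice made after the data were seen, they were 20.9% and 74.2%. A minimum of 5 UMIs in both chains left 1235 cells with chronic GVHD, and at that number the shares were 8.74% and 60.1%. All paired cells thinned to 1235, also chosen later, gave 6.05% and 52.6%, so the drop came with the smaller number of cells. At that equal number the shares were higher with 5 UMIs than over all paired cells, for reasons not tested.

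**Figure D1:**
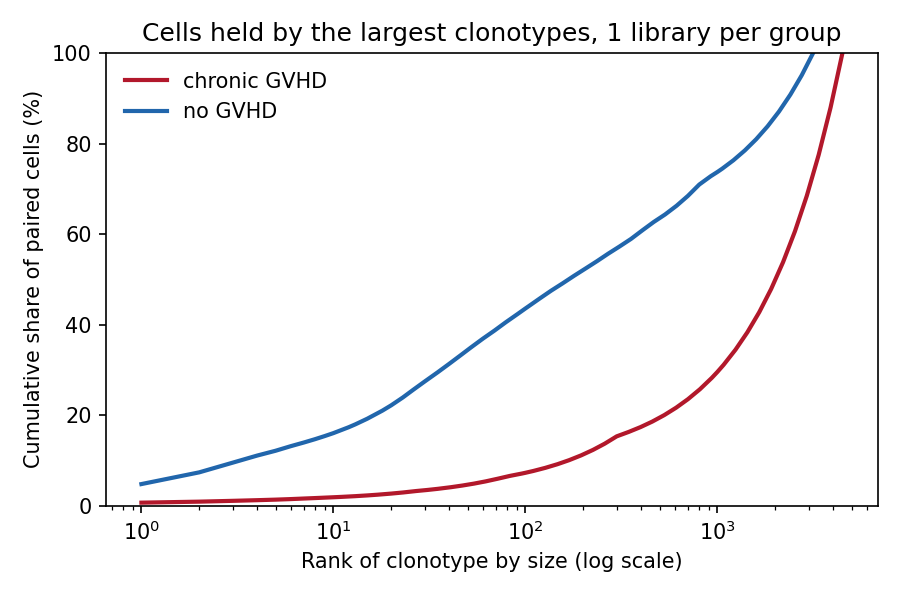
Cumulative share of paired cells (percent, vertical axis) held by clonotypes ranked from largest to smallest (horizontal axis, log scale), 1 line per library. The 10 largest clonotypes held 1.86% of cells with chronic GVHD and 16.03% without GVHD.

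The 10 largest clonotypes held 1.86% of paired cells with chronic GVHD (1.503 to 2.28%) and 16.03% without (15.2 to 16.8%). The largest clonotype without GVHD paired TRAV13D-2 and TRAJ13 (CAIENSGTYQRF) with TRBV13-3 and TRBJ2-5 (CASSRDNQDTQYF) and held 391 cells, 4.77% of the library. It was followed by a TRBV16 clonotype of 212 cells (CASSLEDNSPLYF with TRBJ1-6, TRAV8N-2 with TRAJ37) and by a clonotype named TRBV12-2 of 177 cells (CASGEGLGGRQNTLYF with TRBJ2-4, TRAV4N-4 with TRAJ50). A TRBV31 clonotype (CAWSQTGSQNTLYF) held 126 cells, and another named TRBV12-2 (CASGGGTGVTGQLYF) held 88. With chronic GVHD the largest clonotype paired TRAV12-3 and TRAJ34 (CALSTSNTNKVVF) with TRBV15 and TRBJ2-1 (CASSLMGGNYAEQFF) and held 33 cells, 0.668%. Next came a TRBV16 clonotype of 11 cells (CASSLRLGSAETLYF), a TRBV31 clonotype of 9 (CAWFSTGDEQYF), a TRBV5 clonotype of 7 (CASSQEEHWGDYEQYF) and a TRBV19 clonotype of 6 (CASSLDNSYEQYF). None of these 10 clonotypes had a cell in the other library.

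TRBV26, known as Vβ3 in the older naming, differed between the libraries by the most percentage points of any TRBV segment. It was used by 813 clonotypes without GVHD, 25.8% of the total (24.3 to 27.4%), and by 17 with chronic GVHD, 0.379% (0.221 to 0.607%), a ratio of 68.0 (42.2 to 117). TRBV23 was used by 3.68% of clonotypes without GVHD (3.05 to 4.40%) and by 2 clonotypes, 0.0446% (0.00540 to 0.161%), with chronic GVHD, a ratio of 82.4 (22.3 to 689). TRBV3 took 9.39% (8.39 to 10.5%) without GVHD and 2.03% (1.64 to 2.49%) with chronic GVHD, and TRBV15 took 2.41% (1.90 to 3.01%) and 1.67% (1.32 to 2.09%). By cells the TRBV15 order was the opposite, 1.36% and 2.35%, and with TRBV26 clonotypes left out its shares were 3.25% (2.57 to 4.05%) without GVHD and 1.68% (1.32 to 2.10%) with chronic GVHD. Higher with chronic GVHD were TRBV20 (9.55% against 2.92%), TRBV4 (5.93% against 2.12%), TRBV5 (10.1% against 5.11%) and TRBV13-2 (3.79% against 1.93%). The TRBV13-2 value rests on a name that is not secure, as its CDR3 start is shared with most clonotypes named TRBV12-2. Both names with a CASG start together took 9.75% and 7.90%, and 9.79% and 10.6% with TRBV26 clonotypes left out. Part of these gaps follows from TRBV26 filling the total. With TRBV26 clonotypes left out of both libraries, TRBV20 took 9.59% and 3.93%, TRBV4 5.96% and 2.86%, TRBV5 10.1% and 6.88%, and TRBV13-2 3.81% and 2.61%, while TRBV3 took 2.04% and 12.6%. The distance in TRBV usage was 37.7% with all clonotypes and 21.2% without those of TRBV26. By cells, TRBV26 held 0.486% with chronic GVHD and 13.8% without, and TRBV23 held 0.0405% and 1.78%. All of these V segments lie in the TRB locus on chromosome 6, with TRBV26 at 41227525 to 41227913, TRBV23 at 41216073 to 41216526, TRBV20 at 41188273 to 41188977 and TRBV3 at 41048394 to 41048824 (GRCm38.p6, RefSeq).

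**Figure D2:**
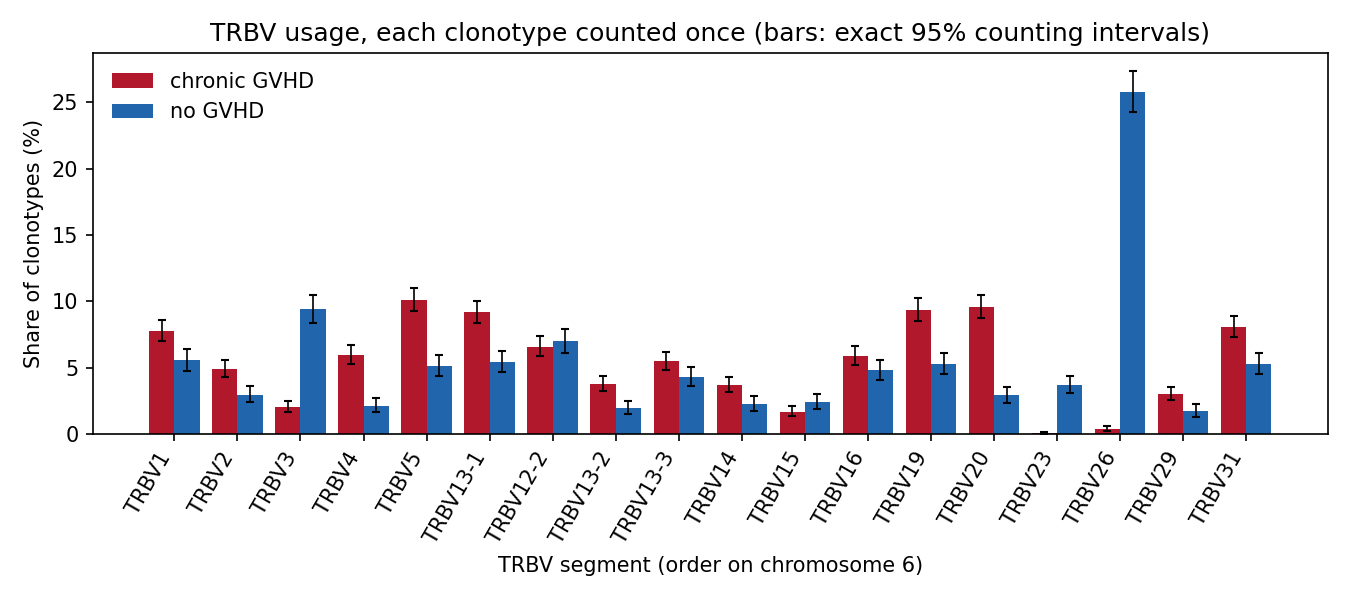
Share of clonotypes (percent) using each TRBV segment with at least 2% in at least 1 library, in chromosomal order, with exact 95% counting intervals as error bars and 1 library per group. TRBV26 stands at 0.379% with chronic GVHD and 25.8% without GVHD.

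Non-productive TRB rearrangements, which encode no receptor chain and are carried along in cells selected for their other TRB, gave a view of segment use without selection on the segment itself. This comparison was chosen after the TRBV shares were seen. Among them TRBV26 took 3.21% with chronic GVHD (2.27 to 4.40%, 37 of 1152) and 4.21% without (3.05 to 5.65%, 42 of 998). The productive TRBV26 share was thus 6.13 times the non-productive share without GVHD, and the non-productive share was 8.47 times the productive share with chronic GVHD. Such contrasts were not particular to TRBV26. For TRBV3 the same ratios were 2.18 without GVHD and 2.09 with chronic GVHD. For TRBV23 the non-productive share was the larger in both libraries, 158 times the productive share with chronic GVHD and 2.51 times without. In the stricter set, also chosen later, TRBV26 took 3.48% (2.31 to 5.02%, 27 of 776) and 1.28% (0.471 to 2.76%, 6 of 469). The order of the libraries turned there. The TRBV26 ratio of chronic GVHD to no GVHD was 0.763 (0.477 to 1.22) in the larger set and 2.72 (1.10 to 8.06) in the stricter set. TRBV3 took 4.25% and 4.31% of non-productive rearrangements (4.51% and 6.82% in the stricter set), and TRBV23 took 7.03% and 9.22% (7.35% and 8.32%). TRBV4 and TRBV20 were higher with chronic GVHD here too, TRBV4 at 10.9% (9.19 to 12.9%) against 6.01% (4.62 to 7.67%) and TRBV20 at 3.91% (2.86 to 5.19%) against 2.004% (1.23 to 3.08%). The TRBV20 ratio was 1.95 (1.13 to 3.48), and 1.49 (0.759 to 3.09) in the stricter set. For TRBV4 the ratio was 1.82 (1.33 to 2.52), and 1.83 (1.18 to 2.92) in the stricter set.

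**Figure D3:**
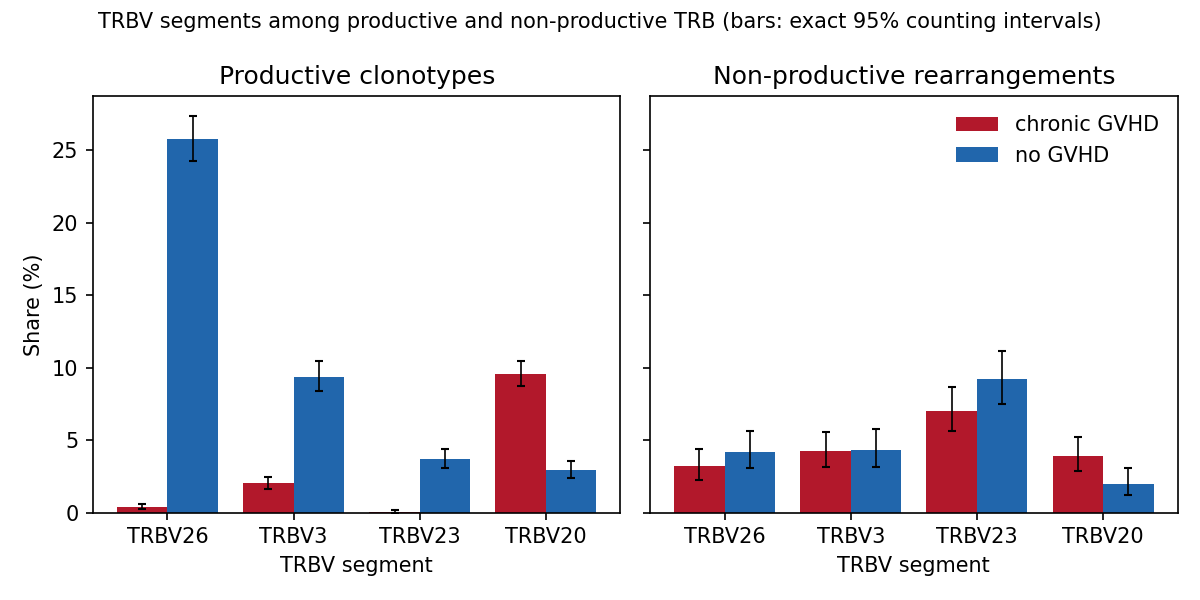
Share (percent) of TRBV26, TRBV3, TRBV23 and TRBV20 among productive clonotypes (left) and among non-productive TRB rearrangements (right), with exact 95% counting intervals as error bars and 1 library per group. TRBV26 took 0.379% and 25.8% of productive clonotypes with and without GVHD, and 3.21% and 4.21% of non-productive rearrangements.

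The Mtv list groups segments whose T cells are deleted by viral superantigens in strains such as BALB/c. Its 5 segments together took 15.1% of clonotypes with chronic GVHD (14.0 to 16.2%) and 40.7% without (39.0 to 42.5%). TRBV26 made up nearly all of this difference, since the other 4 segments took 14.7% (13.7 to 15.8%) and 14.9% (13.7 to 16.2%). With TRBV26 clonotypes left out of the total, these 4 took 14.8% (13.7 to 15.8%) and 20.1% (18.5 to 21.8%). TRBV12-1 took 0.580% and 0.761% of all clonotypes. TRBV16 took 5.87% with chronic GVHD and 4.79% without, but 5.89% and 6.45% once TRBV26 clonotypes were left out. TRBV12-2 as named in the files took 6.58% and 6.98%, but 6.61% (5.90 to 7.38%) and 9.40% (8.25 to 10.7%) with TRBV26 left out and 6.60% and 10.9% by cells. Of the clonotypes so named, 93.2% with chronic GVHD and 85.5% without had a CDR3 beginning with CASG, as did 95.3% and 100% of clonotypes named TRBV13-2 and 0 of those named TRBV12-1. The name TRBV12-2 is therefore uncertain for most of these clonotypes; TRBV12-2 (41118864 to 41119364) and TRBV13-2 (41121396 to 41121832) are neighbors on chromosome 6. TRBV12-2 clonotypes with a CASS start were rare, at 0.0892% with chronic GVHD (0.0243 to 0.228%) and 0.983% without (0.669 to 1.39%). With TRBV12-2 counted only from a CASS start, the whole Mtv list took 8.59% of clonotypes with chronic GVHD and 34.7% without. The comparator list took 40.5% (39.1 to 42.0%) and 25.4% (23.9 to 27.0%), and with TRBV26 left out 40.7% (39.2 to 42.1%) and 34.2% (32.3 to 36.2%). By cells it took 40.04% and 36.1%. Its members TRBV13-1 (9.17% against 5.42%), TRBV19 (9.37% against 5.26%), TRBV1 (7.79% against 5.55%) and TRBV2 (4.93% against 2.95%) were higher with chronic GVHD, but less so with TRBV26 left out. The ratio was then 1.26 (1.05 to 1.51) for TRBV13-1, 1.33 (1.11 to 1.60) for TRBV19, 1.05 (0.869 to 1.26) for TRBV1 and 1.25 (0.973 to 1.604) for TRBV2. TRBV13-3 took 5.47% and 4.28%, but 5.49% and 5.77% with TRBV26 left out and 5.46% and 10.6% by cells. The comparator list also holds the uncertain name TRBV13-2.

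By clonotypes, usage of the other segment families lay closer together than TRBV usage. The distance was 12.4% for TRAV subgroups, 7.99% for TRAJ and 4.56% for TRBJ. By cells it was 20.4%, 18.9% and 9.67%, against 30.8% for TRBV. TRAV12-3 (5.13% against 3.14%) and TRAV6-7 (8.39% against 5.55%) were higher with chronic GVHD, and TRAV8-1 took 2.01% and 1.40%, TRAV6-5 3.03% and 2.28%. TRAV7-2 (2.57% against 4.88%), TRAV10 (3.101% against 4.54%), TRAV14-2 (3.30% against 4.38%) and TRAV9-2 (1.83% against 2.41%) had the smallest ratios of chronic GVHD to no GVHD. Among TRAJ, TRAJ49 took 3.19% with chronic GVHD and 2.09% without, TRAJ18 2.95% and 1.998% (1.47% and 1.97% without its joins to TRAV11), and TRAJ34 4.02% and 3.20%. The smallest ratios were those of TRAJ7 (1.20% against 2.47%), TRAJ44 (1.78% against 2.54%) and TRAJ15 (2.90% against 3.39%). TRBJ1-5 took 3.61% and 2.12%, TRBJ2-4 10.3% and 8.56%, and TRBJ1-1 9.48% and 11.4%. TRBJ1-2 took 5.29% and 5.87%, an order that turned, to 5.26% and 4.83%, with TRBV26 clonotypes left out. The interval of the ratio held 1 for TRAV8-1, TRAV6-5, TRAV9-2, TRAJ34, TRAJ15 and TRBJ1-2, which were thus not resolved at this depth. It lay only just apart from 1 for TRAJ18 (1.08 to 2.02), TRBJ2-4 (1.03 to 1.404), TRBJ1-1 (0.718 to 0.956), TRAV14-2 (0.594 to 0.958) and TRAJ44 (0.509 to 0.971). With TRBV26 clonotypes left out it also held 1 for TRAJ7 (1.21% and 1.71%), TRAJ18, TRBJ1-1 and TRAV14-2. Counted by cells, TRBJ2-4 (10.2% and 12.5%), TRBJ1-1, TRBJ1-2, TRAV14-2 and TRAJ15 stood in the opposite order. The TRAV7-2 shares lay closer together by cells, at 2.67% with chronic GVHD and 3.03% without.

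Receptors of iNKT cells, a lipid-reactive lineage that is abundant in mouse liver and can carry CD4, were found almost only with chronic GVHD. Counting any productive TRA of a cell, they were carried by 70 of 4942 paired cells with chronic GVHD, 1.42% (1.11 to 1.79%), and by 3 of 8191 without, 0.0366% (0.00755 to 0.107%), a ratio of 38.7 (12.7 to 192). With each clonotype counted once the ratio was 15.9 (5.23 to 79.2). The 70 cells belonged to 68 clonotypes and the 3 cells to 3. Each of these 3 cells carried a second TRA or TRB, so that 0 of 6317 cells with exactly 1 TRA and 1 TRB had the receptor without GVHD (limit 0.0475%), against 65 of 4036 with chronic GVHD (1.61%). The dominant TRA alone, a rule added after the data were seen, gave 68 and 1 cells in 66 and 1 clonotypes. The clonotype ratio was then 46.4 (8.05 to 1861). TRAV11 joined to TRAJ18 gave the CDR3 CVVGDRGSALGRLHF in 63 of the 70 cells, through 5 nucleotide versions. Their TRB was named TRBV12-2 in 38 cells (54.3%), TRBV1 in 10, TRBV29 in 7 and TRBV13-1 in 6. A CASG start under the name TRBV12-2 or TRBV13-2 was present in 39 of the 70 (55.7%, 43.3 to 67.6%). The 3 cells without GVHD used TRBV15, TRBV19 and TRBV26. With a minimum of 5 UMIs in both chains the difference was 2.15 percentage points, against 1.38 over all paired cells. No MAIT receptor was found, and a count of 0 allows a share of up to 0.0607% with chronic GVHD and 0.0366% without.

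CDR3 features that have been linked to self-reactivity or to the timing of rearrangement showed small differences. The mean TRB CDR3 was 14.1 amino acids long with chronic GVHD (SD 1.44 over 4482 clonotypes) and 13.9 without (SD 1.30 over 3153), a difference of 0.254. TRBV26 clonotypes without GVHD averaged 13.7 and other clonotypes of that library 14.0. Hydrophobic residues at both positions 6 and 7 of the TRB CDR3 were present in 2.72% of clonotypes with chronic GVHD (2.27 to 3.24%) and 2.16% without (1.68 to 2.73%), a ratio of 1.26 (0.931 to 1.72). TRAJ segments at the end of the cluster nearest to the V segments, TRAJ38 and higher numbers, took 36.0% (34.6 to 37.4%) and 34.3% (32.7 to 36.0%). The sign of this last difference turned under other settings, to -3.97 percentage points with a minimum of 5 UMIs in both chains and to -0.318 with TRBV26 clonotypes left out.

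The libraries shared no paired clonotype, by nucleotide or by amino acid sequence. Among TRB sequences, 3 were identical at the nucleotide level in both libraries: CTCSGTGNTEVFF and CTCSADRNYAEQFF with TRBV1, and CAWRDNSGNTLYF with TRBV31. In each case the TRA partners differed between the libraries. At the amino acid level 16 TRB were shared, of 4286 with chronic GVHD and 2541 without. These covered 22 and 91 cells, of which 54 without GVHD carried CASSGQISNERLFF with TRBV13-1. The shared sequences were listed after their values were seen. Of the 90 barcodes called as cells in both libraries, 0 carried the same TRB.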

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

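The signals in this part lie in contigs outside the paired productive chains, and each was higher with chronic GVHD; all were chosen after the data were seen. Contigs of called cells that joined a TRDV segment to a TRAJ segment made up 0.539% with chronic GVHD and 0.360% without. Contigs without a V segment made up 28.9% of TRB contigs of called cells with chronic GVHD and 26.8% without. Non-productive full-length contigs made up 9.91% of TRB contigs of called cells with chronic GVHD and 7.87% without. Among productive TRA contigs of barcodes not called as cells, TRAV11 joined to TRAJ18 made up 1.22% with chronic GVHD (19 of 1556) and 0% without (0 of 5284, which allows a share of up to 0.0568%).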

How the results depend on the processing

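The alternatives that leave out TRBV26, split clonotypes by size, use the CDR3 start of TRBV12-2, apply 2 UMIs to the paired share, read iNKT receptors from the dominant TRA, group the paired cells by TRB, or thin to 1235 cells were chosen after the data were seen. No paired analysis was possible because each group held 1 library. Each alternative was judged against a tolerance, which for shares was the counting interval. It was a fixed factor for the ratio of distinct clonotypes and a sampling spread over clonotypes for CDR3 length and TRBV distance. For shared clonotypes it was an equal count. Of 109 alternatives for the main results, 67 stayed within the tolerance, 42 moved beyond it, and 4, all of the TRAJ difference, turned its sign. Of 291 for the named segments, 224 stayed, 67 moved and 14 turned the sign. Counting each cell turned 9 of these: TRBV13-3 (5.46% against 10.6%), TRBV15 (2.35% against 1.36%), TRBJ2-4 (10.2% against 12.5%), TRBV16, TRBV12-1, TRBJ1-1, TRBJ1-2, TRAV14-2 and TRAJ15. Leaving out TRBV26 turned TRBJ1-2, TRBV16 and TRBV13-3, and TRBV12-2 turned with 5 UMIs and by TRB alone. The expanded, top 10, Mtv, iNKT, CDR3 length and hydrophobic differences kept their sign in all alternatives, and the ratio of distinct clonotypes ran from 1.65 to 2.36. Alternatives by TRB alone used all cells with a usable TRB, so the cell set changed with the definition. Those with 5 UMIs kept 1235 and 3172 paired cells, so depth changed too. The TRAJ difference could not be computed for TRB alone. Leaving out shared clonotypes changed nothing, as 0 were shared, so all its alternatives were bound to count as stayed. The cause of each shift was not tested except where the alternative itself removes TRBV26 and, for the expanded shares with 5 UMIs, by thinning all paired cells to 1235.

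Differences are chronic GVHD minus no GVHD, in percentage points. The expanded difference, -51.3, became -55.0 with exactly 1 TRA and 1 TRB, -52.4 with 2 UMIs, -51.35 with 5 UMIs, -46.56 with all paired cells thinned to 1235, -54.5 without cells of 2 or more TRB, -46.6 by TRB alone, -53.3 by TRB within the paired cells, -47.8 by Cell Ranger identifier, -49.6 at the deeper thinning, -50.1 from 3 cells and -58.2 without TRBV26. The top 10 difference, -14.2, became -17.0 with exactly 1 TRA and 1 TRB, -14.8 with 2 UMIs, -20.0 with 5 UMIs, -16.1 without cells of 2 or more TRB, -15.2 by TRB alone, -11.2 without the largest clonotype and -16.7 without TRBV26. The Mtv difference, -25.6, became -20.2 with 5 UMIs, -28.0 by TRB alone, -16.8 by cell, -0.235 with TRBV26 off the list, -26.1 with TRBV12-2 counted only from a CASS start, -27.8 in single-cell clonotypes and -19.6 in larger ones. The iNKT difference, 1.38, became 1.61 with exactly 1 TRA and 1 TRB, where 0 cells remained without GVHD, 2.15 with 5 UMIs, 1.03 by TRB alone and 1.43 in single-cell clonotypes.

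The TRAJ difference, 1.62, became -3.97 with 5 UMIs, -0.434 by cell, -0.318 without TRBV26 and 2.60 from TRAJ45, and was -0.0783 with 2 UMIs. The TRBV distance, 37.7%, became 32.7% with 5 UMIs, 30.8% by cell and 21.2% without TRBV26. The CDR3 length difference, 0.254 amino acids, became 0.176 by cell and 0.181 without TRBV26. The hydrophobic difference, 0.565, became 0.827 with the conserved cysteine not counted. Shared clonotypes, 0 by both chains, numbered 4 by TRB alone over all cells with a usable TRB and 3 by TRB within the paired cells. The paired share difference, -7.29, became -13.8 with 2 UMIs.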

Other observations

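TRBV26 clonotypes without GVHD were numerous but small. Each held 1.39 cells on average, against 3.02 for the other clonotypes of that library, and 17.5% were expanded (14.9 to 20.3%) against 29.7% (27.9 to 31.6%). With chronic GVHD the order was the opposite, with 1.41 cells per TRBV26 clonotype against 1.101 and 23.5% expanded (6.81 to 49.9%, 4 of 17) against 6.65% (5.94 to 7.42%). Without GVHD, TRBV26 took 29.0% of single-cell clonotypes, 17.0% of expanded clonotypes and 5.41% (6 of 111) of clonotypes with 10 or more cells. Its partners leaned mildly to TRAV14-3 (10.5% against 6.62% in other clonotypes) and TRAV7-2 (6.89% against 4.19%). The barcodes not called as cells mirrored the difference, with TRBV26 in 12.7% of their productive TRB contigs without GVHD and 0.620% with chronic GVHD.

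TRB amino acid sequences encoded by 2 or more nucleotide versions made up 0.513% with chronic GVHD (0.322 to 0.776%) and 1.18% without (0.798 to 1.68%). Paired cells with 2 or more productive TRA made up 11.01% (10.1 to 11.9%) and 15.8% (15.002 to 16.6%).

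The tests below were made on patterns already seen. Chosen after the result was seen were those on libraries per group, on the number of TRBV26 sequences, on TRBJ usage and the other Mtv segments, and on clonotype counting and TRA recovery for iNKT receptors. The higher expansion without GVHD stayed at 66.7% at equal cell number, against 15.4%, so the number of cells does not account for it. Without thinning it was 67.6% over 3172 cells with 5 or more UMIs in both chains, against 71.7% over all 8191 paired cells, which argues against free RNA of large clones. Barcode errors that make 1 cell look like several stay undecided. While 0% of the expanded cells had a barcode 1 base from another cell of their clonotype, so had 0 of all 22017 barcodes listed without GVHD, so this test could not come out otherwise. Animals, cell preparation or a label swap cannot be told apart from the disease, because there was 1 library per group. The disease state itself, and how the mice without GVHD were prepared, stay open and untested.

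The TRBV26 share without GVHD was 4.21% among non-productive rearrangements and 1.28% in their stricter set. This argues against capture or naming of the segment as the whole cause. The productive TRBV26 share without GVHD was 23.8% among clonotypes of cells with 1 TRA and 1 TRB of 5 or more UMIs, against doublets and free RNA. Distinct CDR3 amounted to 87.8% of TRBV26 clonotypes and their TRBJ usage lay 11.5% from that of the others, against split clones and against a single specificity tied to a TRBJ. With TRBV26 clonotypes left out, the share of the other Mtv segments without GVHD was 1.36 times (1.21 to 1.54) that with chronic GVHD, far below the TRBV26 ratio of 68.0 (42.2 to 117). With the uncertain TRBV12-2 counted only from a CASS start it was 1.46 times (1.25 to 1.71). By member the ratio was 1.76 (0.968 to 3.19) for TRBV12-1, 1.10 (0.891 to 1.34) for TRBV16 and 1.93 (1.39 to 2.70) for TRBV15. The whole list thus did not share the TRBV26 difference between the libraries alike. A loss common to both libraries leaves such ratios unchanged, so they cannot speak on it. Non-productive shares were 7.18 and 4.48 times the productive shares for TRBV12-1, with chronic GVHD and without. They were 3.53 and 2.33 times for TRBV15, and 0.843 and 1.11 times for TRBV16. In the ratio between libraries, TRBV12-2 with a CASS start stood at 14.8 (5.23 to 57.7) on 31 and 4 clonotypes. An effect like that on TRBV26 stays open for this member. A superantigen that acts on TRBV26, alone or with this member, was not tested and stays open, as do differences between the animals; TRBV3 and TRBV23, which are not on the list, were also higher without GVHD.

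For the iNKT receptors, the lower bound of the ratio was 5.23 with each clonotype counted once and any TRA of a cell counted, and 8.05 by the dominant TRA alone, so dilution by large clones does not account for their rarity without GVHD. TRA was found in 85.1% of called cells without GVHD, more than with chronic GVHD. By the dominant TRA, TRAJ18 joined to V segments other than TRAV11 was used by 62 clonotypes without GVHD and 66 with chronic GVHD, which argues against a failure to capture TRAJ18. A difference in the sort, in the animals or with the disease stays open and was not tested.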
